A study of Homo sapiens with 6 samples.

How the data were processed

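Polyadenylated RNA from 3 wild-type and 3 CXCdel knock-in K562 libraries was extracted with an RNeasy Plus kit and made into QuantSeq 3' mRNA-Seq FWD libraries, per the labels' protocols. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Reads were processed with STAR 2.7.0e, HTSeq 0.6.1 and DESeq2, with the builds GRCh38 and hg38, per the submitters' processing notes. The annotation, the strand setting of the counting, the DESeq2 version and its settings are not given in the sources used here. Without the strand setting, reads of antisense or overlapping genes cannot be assigned with certainty, and near-identical genes may share reads.

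The deposited table holds the authors' comparison of the 2 kinds of cells and no values per library. The signal column is the authors' mean normalised count over the 6 libraries, per the file headers. The log2 fold change and its SE are the authors', per the file headers, and the direction is not stated. The score used for ranking genes is the deposited test statistic, per the file headers. The p-value and adjusted p-value are the authors' deposited values from DESeq2, per the file headers and the submitters' processing notes. Checks on the values showed that the deposited p equals the two-sided normal p of the statistic within 1% for each gene, and that Benjamini-Hochberg adjustment over the listed genes gives the deposited adjusted p within 4.7e-04. The fold changes appear moderated towards 0: the SE never exceeds 0.282, and for 4433 genes (28.3%), all with a mean count under 20, it lies below counting error. The statistic lies within 5% of fold over SE for 15374 genes and differs by more for 296, with ratios from 0.51 to 1.55. If the folds are moderated, those of genes with few counts understate the difference.

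The plan was a test on counts per library. Because the table holds only the comparison, its adjusted p under 0.05 was used as the gene test, as the plan provided, and no count model was fitted. Of the gene IDs, 14089 paired with a symbol and 1581 did not. Coordinates and gene classes came from GENCODE 29 (GRCh38), which held 15513 of the IDs and lacked 157. Before the data were examined, 35 gene lists and the naming rule were fixed. Named are EZH2, EZH1, DNMT1 and LIN54, the 10 largest positive and 10 largest negative log2 fold changes past the test with a mean count of at least 20 and a symbol, up to 4 members per list with the smallest adjusted p among those past the test, and, in lists with none, up to 2 members with the highest mean count. Some genes that the rule takes are not reported here. Genes named in the closing section outside this rule were chosen after their values were seen.

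Lists with at least 5 measured genes were tested, two-sided, with cameraPR of limma 3.58.1 (R 4.3.3) on the statistic, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 35 lists. An estimated correlation needs values per library and was not computed, so the list p-values rest on the preset value. List members absent from the 15670 genes were left out. Measured were 50 of 132 developmental regulators, 23 of 39 HOX genes, 30 of 85 germline genes and 36 of 87 histone genes. Of 33 lymphoid and 41 chemokine genes, 6 and 5 were measured. Position was scanned in windows of 5 Mb with at least 8 genes of mean count at least 50 (9327 genes), each window's median set against random draws of as many genes, with adjustment over the windows; the smallest p that 100000 resamples can give is 1e-05. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were a stricter adjusted p, a bound on the fold, a mean count of at least 20, recomputed adjusted p-values, ranks or log2 fold changes in the list test and 10000 random lists matched on mean count. Added after the values were seen were leaving out the shifted parts of chromosomes 7 and 1, protein-coding genes only, and each list without its most changed member.

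The steps were tested on simulated data. In simulated statistics for the 15670 genes of this comparison, made with the deposited SE and 200 changed genes, 21.5% were recovered at a log2 change of 0.5, 82.5% at 1 and 100% at 2; since the deposited SE of genes with few counts is too small, these shares are upper estimates. With no list shifted, 1 of 100 simulated tables had any list past the test. With the stress-response list shifted by 1 unit of the statistic, it was called with the right sign in 100 of 100. Each gene was drawn independently, so these numbers do not measure false list calls where members of a list vary together.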

Results

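K562 is a human cell line grown from a chronic myeloid leukaemia, with erythroid and megakaryocytic features. RNA was measured in 3 libraries of wild-type K562 cells and 3 libraries of K562 cells that carry a knock-in called CXCdel, with 3' tag sequencing (QuantSeq), which reads the ends of polyadenylated transcripts. The comparison asks which transcripts differ between the 2 kinds of cells. The authors' deposited table lists 15670 genes, each with 1 mean normalised count over the 6 libraries, a log2 fold change, its standard error (SE) and an adjusted p from DESeq2. The mean normalised counts add up to 8344638, with a median of 104 per gene and a range from 2.24 to 204769 (MT-RNR2, 2.45% of the sum). The table gives 1 mean per gene, so the depth of each library is unknown, and every error below is the SE of the authors' model. The table does not state which kind of cells is the numerator of the fold change. Values are therefore given with their deposited sign, as a positive and a negative side, and no gene is called higher in wild-type or in CXCdel cells.

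The labels do not name the gene that carries CXCdel. Among the genes with a CXC or CXXC domain chosen in advance, EZH2, the catalytic subunit of Polycomb repressive complex PRC2, lay on the negative side in the authors' deposited table at −1.41 ± 0.094 (SE, log2), a ratio of 0.376, with an adjusted p of 3.5e-48 (DESeq2) and a mean normalised count of 2119. EZH1, its paralog, was at −0.45 ± 0.182 (adjusted p = 0.076), DNMT1, the maintenance DNA methyltransferase, at −0.15 ± 0.079 (0.19) and LIN54, the DNA-binding subunit of MuvB, at −0.07 ± 0.185 (0.88). These 3 genes did not pass the test. A 3' tag counts transcript ends and does not read a CXC domain, so these values do not check the edit. EZH2 lies on chromosome 7 from 148807383 to 148884321 (GRCh38), inside a stretch from 130 to 150 Mb where 60 of 62 genes with a mean count of at least 50 had negative values, with a median of −0.84.

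In the authors' deposited table, 2486 of the 15670 genes (15.9%) had an adjusted p under 0.05 (DESeq2), 1231 on the positive side and 1255 on the negative side. Most differences were modest: the median absolute log2 fold change of these genes was 0.61, and 84 reached 2, of which 52 were positive and 32 negative. The largest positive values belonged to KIF1A, a kinesin of axonal transport (5.49 ± 0.223), ENAH, an actin regulator (4.92 ± 0.211), the transcription factor ZFHX3 (4.30 ± 0.251), CECR2, a bromodomain protein of chromatin remodelling complexes (4.20 ± 0.239), and SPARC, a matrix glycoprotein (4.18 ± 0.247). ZNF827 (4.15), the forkhead factor FOXN3 (4.12), the mitochondrial complex I subunit MT-ND6 (4.08), PRTG (4.02) and NXN (4.01) followed. On the negative side the largest values were those of PRSS2, a trypsinogen (−4.41 ± 0.133), the homeobox gene OTP (−4.38 ± 0.247), CLEC2L (−4.22 ± 0.247), the cancer-testis antigen PASD1 (−3.27 ± 0.202) and TRBC1, a T cell receptor beta constant gene (−3.25 ± 0.260). CEP41 (−3.10), DHRS2 (−2.99), LINGO1 (−2.82), LINC02964 (−2.67) and ADGRL3 (−2.66) completed the 10. For several of these genes the adjusted p (DESeq2) was weaker than the fold over its SE would give. Examples are ZFHX3 (1.5e-17) and OTP (1.9e-21), so the SE overstates their precision. PRSS2, CLEC2L, TRBC1 and CEP41 all lie on distal chromosome 7. PRSS2 has near-identical copies, and its reads may be shared with them.

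**Figure D1:**
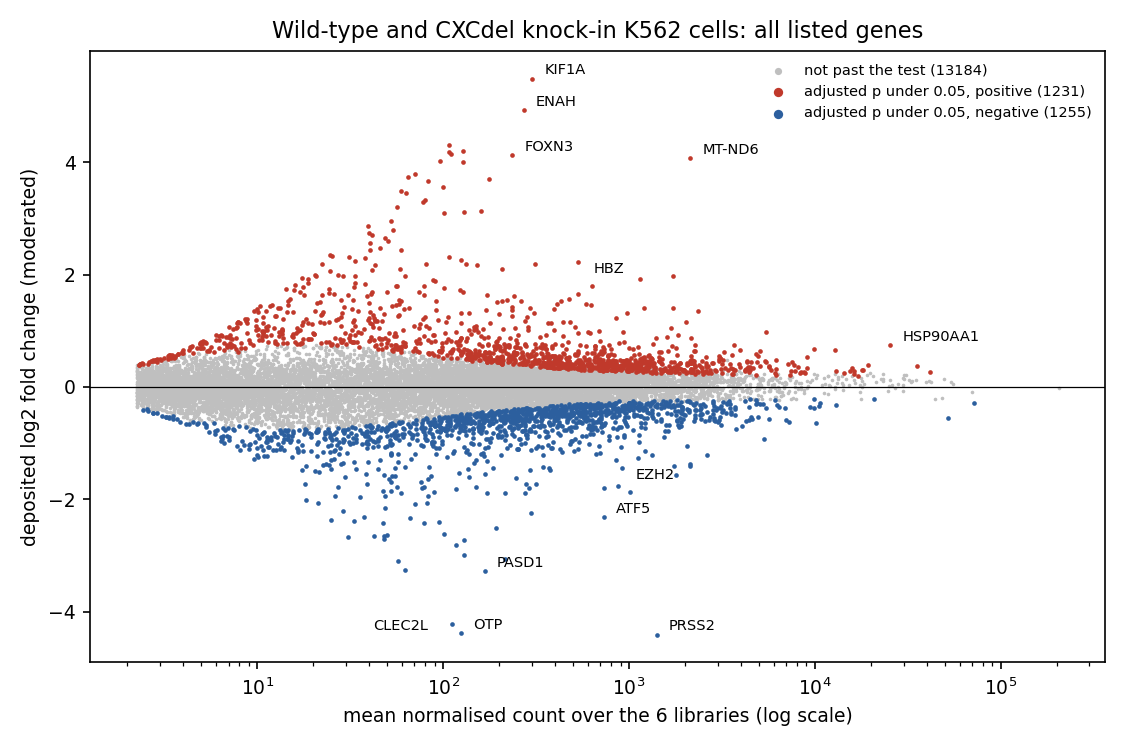
Deposited log2 fold change (moderated) against the mean normalised count over the 6 libraries (log scale), 1 point per gene. Red and blue points are the 1231 positive and 1255 negative genes with an adjusted p under 0.05, and grey points the other 13184; EZH2 lies on the negative side at −1.41.

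The lists of HOX genes and of developmental regulators passed the list test on the positive side, whereas the Polycomb subunits as a group did not pass. Of 50 measured developmental regulators that are often Polycomb targets, 14 passed the gene test on the positive side and 4 on the negative side (16 and 5 adjusted over the list alone), with a list adjusted p of 0.0014 (limma cameraPR). Examples in the authors' deposited table are PAX3 (3.74 ± 0.266), POU3F2 (2.71 ± 0.271), GATA3 (1.83 ± 0.263) and FOXA2 (1.24 ± 0.205). The adjusted p of PAX3, 2.9e-13 (DESeq2), was weaker than its fold over SE would give. Of 23 HOX genes, 10 were positive and 1 negative (10 and 2 adjusted over the list alone; adjusted p = 0.0091), among them HOXC13 (1.69 ± 0.282), HOXD3 (1.35 ± 0.269) and HOXD4 (0.92 ± 0.246). These 3 had mean counts under 20, and among the 11 HOX genes with a mean of at least 20 the list lost its call and turned to the negative side (adjusted p = 0.76). In the PRC2 list (13 genes, adjusted p = 0.14) EED, which binds trimethylated H3K27, was positive (0.31 ± 0.107) and EZH2 negative (2 and 3 adjusted over the list alone). The PRC1 list (21 genes, 0.57) held PHC2 (−0.44) and CBX7 (−0.71) on the negative side and none on the positive (0 and 2 adjusted over the list alone; 4 positive at an unadjusted DESeq2 p under 0.05). DNA methylation genes (23, 0.33) had 2 positive calls, DNMT3A, a de novo methyltransferase (1.02 ± 0.143), and PCNA (0.48), and 1 negative call, the same numbers as adjusted over the list alone. Trithorax-group and H3K36 methyltransferase genes (22, 0.77) included KMT2C, on distal chromosome 7 (−0.45), KDM5A (0.30) and KMT2A (−0.30), again 1 positive and 2 negative adjusted over the list alone. Germline and cancer-testis genes (30, 0.49) had 5 positive and 2 negative calls under both adjustments, with MAGEC2 (2.56), MAGEC1 (1.67) and MAGEB2 (0.97) positive and CTCFL (−0.57) negative. Reads may be shared among MAGE genes. Imprinted genes (20, 0.14) had 1 positive and 5 negative calls (2 and 5 adjusted over the list alone), among them PHLDA2 (−0.73), SLC22A18 (−1.17), DIRAS3 (−0.78) and GRB10 (−0.37).

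Interferon-response and antigen-presentation genes also lay on the positive side. Of 45 interferon-response genes, 12 were positive and 1 negative (14 and 1 adjusted over the list alone; cameraPR adjusted p = 0.0027). In the authors' deposited table the immunoproteasome subunit PSMB9 was at 1.68 ± 0.222, UBE2L6, an enzyme that attaches ISG15, at 1.26 ± 0.151 and BST2, a factor that tethers virions, at 0.74 ± 0.122, while IFITM3 was at −0.71 ± 0.107. Of 16 MHC class I and II genes, 5 were positive and 1 negative (6 and 1 adjusted over the list alone; adjusted p = 0.0091), with HLA-C (2.44 ± 0.272), HLA-B (2.09 ± 0.269), the peptide transporter TAP2 (0.60 ± 0.121) and B2M (0.55 ± 0.108). HLA-B and HLA-C had mean counts of 41.4 and 40.5, and their annotated spans overlap on the same strand. Reads may be split between them. Without HLA-C the MHC list did not pass (adjusted p = 0.08), nor did it with ranks in place of the statistic (0.22) or against random lists matched on mean count (0.6).

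Megakaryocyte genes lay on the negative side, and erythroid genes went both ways. Of 25 megakaryocyte and platelet genes, 12 were negative and 1 positive, the same numbers as adjusted over the list alone (cameraPR adjusted p = 0.0014). In the authors' deposited table the tetraspanin CD9 was at −1.86 ± 0.238 and ARHGAP6 at −0.93 ± 0.129, while SPARC was the positive member. The thromboxane synthase TBXAS1, at −1.33 ± 0.235, lies on distal chromosome 7, where most genes were negative. With the log2 fold change in place of the statistic the list did not pass (0.091). Of 47 erythroid genes, 8 were positive and 9 negative (11 and 12 adjusted over the list alone; adjusted p = 0.98). The embryonic globin HBZ was at 1.92 ± 0.110, the delta globin HBD at 1.69 ± 0.188, ALAS2, the first enzyme of erythroid haem synthesis, at 1.15 ± 0.122, and the blood group gene KEL, on distal chromosome 7, at −1.73 ± 0.148. Of the erythroid genes 8 lie on chromosome 7 beyond 105 Mb or on chromosome 1 up to 121.2 Mb, where the median of all genes was negative. Without these parts the list turned from the negative to the positive side without passing (adjusted p = 0.082). Myeloid genes (21, adjusted p = 0.77) had 4 positive and 1 negative calls (5 and 1 adjusted over the list alone), with FCGR2A at −1.57 and LYZ (0.74), ITGAM (0.96) and TYROBP (0.71) positive. Stem and progenitor genes (14, 0.77) had 2 positive and 3 negative under both adjustments, among them ALDH1A1 (1.15, mean count only 17.7), HHEX (−0.44), ANGPT1 (−0.39) and MYB (−0.34). As markers of other cell types, none of 6 lymphoid genes passed DESeq2's test, adjusted or at an unadjusted p under 0.05 (list 0.78; CD3D at 0.19), nor did any of 5 chemokine and receptor genes (0.77; CXCL3 at 0.21 and CCR10 at −0.29). Fibroblast, epithelial and endothelial markers (16, 0.77) had KRT19 (0.69) positive and KRT8 (−0.47), PECAM1 (−1.12) and TAGLN (−0.76) negative, the same numbers as adjusted over the list alone.

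Genes of the integrated stress and unfolded protein response lay on the negative side, and heat shock, sterol and respiratory chain genes on the positive side. Of 48 stress-response genes, 23 were negative and 1 positive (24 and 1 adjusted over the list alone), with a median of −0.27 and the smallest adjusted p of the 35 lists, 3.7e-11 (cameraPR). ATF5, a transcription factor of that response, was at −2.32 ± 0.120 in the authors' deposited table, the amino acid enzyme CTH at −1.08 ± 0.142, the pseudokinase TRIB3 at −0.70 ± 0.090 and DDIT4, an inhibitor of mTORC1, at −0.63 ± 0.087. Of the stress-response genes 7, CTH among them, lie in the shifted parts of chromosomes 7 and 1. Without these parts the list still passed (cameraPR adjusted p = 4.2e-09). Of 21 heat shock genes, 10 were positive and none negative (11 and 0 adjusted over the list alone and also at an unadjusted DESeq2 p under 0.05; 1.1e-06), with the chaperones HSPH1 (0.87 ± 0.086), DNAJA1 (0.76 ± 0.095) and HSP90AA1 (0.74 ± 0.074) and the co-chaperone CHORDC1 (0.77 ± 0.126). Of 32 cholesterol genes, 14 were positive and 2 negative (16 and 3 adjusted over the list alone; 4.1e-05). In the authors' deposited table the fatty acid synthase FASN was at 0.66 ± 0.119, ACAT2 at 0.54 ± 0.082 and HMGCS1, HMG-CoA synthase, at 0.44 ± 0.085. Of 74 nuclear genes of oxidative phosphorylation, 22 were positive and 1 negative (23 and 1 adjusted over the list alone; 4.1e-05), with NDUFA4 (0.52), NDUFA2 (0.47) and COX6B1 (0.47) positive and NDUFB2, on distal chromosome 7, at −0.60. The 15 mitochondrially encoded genes had 3 positive calls, MT-ND6, MT-ND1 (0.65) and MT-ND2 (0.38), and 1 negative, MT-ND4 (−0.55), or 3 and 2 adjusted over the list alone. That list passed with a positive mean of 0.27 and an adjusted p of 0.0022 but had a median of −0.02. Without MT-ND6 it turned to the negative side with an adjusted p of 1, as it did with ranks (0.84) and matched random lists (0.48), and with log2 fold changes it missed the threshold (0.07). Glycolysis and hypoxia genes (39, 0.34) went both ways, with 9 positive and 6 negative calls (11 and 6 adjusted over the list alone), among them PDK3 (3.79), PKM (0.89), VEGFA (−0.98) and the glucose transporter SLC2A1 (−0.75).

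Of 54 MYC and ribosome biogenesis genes, 14 were positive and 1 negative (16 and 2 adjusted over the list alone; cameraPR adjusted p = 0.0036), with HSPE1 (0.73 ± 0.147), POLR1B (0.46 ± 0.116), NOP56 (0.42 ± 0.084) and PHB1 (0.38 ± 0.087) in the authors' deposited table. Of 79 cytosolic ribosomal protein genes, 7 were positive and 2 negative (4 and 0 adjusted over the list alone; 0.0022), with small values such as those of RPL31 (0.33), RPL38 (0.30), RPL23 (0.28) and RPL37 (0.26). With log2 fold changes in place of the statistic neither list passed (0.1 and 0.14). Of 36 replication-dependent histone genes, 11 were negative and none positive under both adjustments (12 and 1 at an unadjusted DESeq2 p under 0.05; list 0.0027), with H4C8 (−1.21 ± 0.157), H2BC21 (−1.05 ± 0.134), H2BC5 (−0.76 ± 0.166) and H1-2 (−0.64 ± 0.093). Most such histone mRNAs lack a poly(A) tail and the genes resemble each other, so these counts are uncertain, and against matched random lists the list did not pass (0.09). Of the cell cycle lists, none passed. G2/M genes (62, 0.42) had 4 positive and 2 negative calls (2 and 2 adjusted over the list alone), among them CCNA2 (0.34), ASPM (0.24), CENPE (−0.33) and HMMR (−0.32). Replication genes (64, 0.77) had 3 and 3 under both adjustments, among them PCNA, GINS2 (0.41), BRCA1 (−0.43) and CDC45 (−0.31). Genes listed with DREAM and MuvB (15, 0.42) had 0 positive and 3 negative calls over all genes and adjusted over the list alone (1 and 3 at an unadjusted p under 0.05). The 3 were RBL1 (−0.72), TESMIN (−0.49) and TFDP2 (−0.27), and whether each is a subunit was not checked.

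Adhesion genes were the last list past the test, and the signalling lists did not pass. Of 27 adhesion and integrin genes, 7 were positive and 1 negative (9 and 1 adjusted over the list alone; cameraPR adjusted p = 0.041), with the integrin ITGB2 (1.42 ± 0.154), the hyaluronan receptor CD44 (1.17 ± 0.140), ITGB7 (1.05 ± 0.28, mean count only 12.2) and CD47 (0.48 ± 0.100) in the authors' deposited table. This list missed the threshold without ITGB2 (0.2), with ranks (0.25), with log2 fold changes (0.055), among genes with a mean of at least 20 (0.09) and against matched random lists (0.35). Targets of p53 (25, 0.23) had 5 positive and 3 negative calls (7 and 3 adjusted over the list alone), among them FDXR (0.73), RPS27L (0.50), GDF15 (−0.62) and TNFRSF10B (−0.50). Immediate early genes (34, 0.57) had EGR1 (0.74) positive and JUN (−1.19) and KLF6 (−0.60) negative, the same numbers as adjusted over the list alone. NF-kB targets (22, 0.23) had 0 positive and 3 negative calls (0 and 4 adjusted over the list alone, 1 and 4 at an unadjusted p under 0.05), TNFAIP3 (−1.81), CD83 (−0.93, mean count only 11.5) and CFLAR (−0.42). TGF-beta targets (17, 0.11) had SKIL (1.07), ID3 (1.05) and PMEPA1 (0.61, mean count only 3.98) positive and ID1 (−0.62) negative (5 and 1 adjusted over the list alone). STAT5 and BCR-ABL output genes (23, 0.77) had 2 positive and 5 negative calls under both adjustments, among them EGR1, CISH (0.45), PIM2 (−0.44) and ID1. In the erythroid, myeloid, stem and progenitor, immediate early and STAT5 lists the median, the mean and the test differed in sign.

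**Figure D2:**
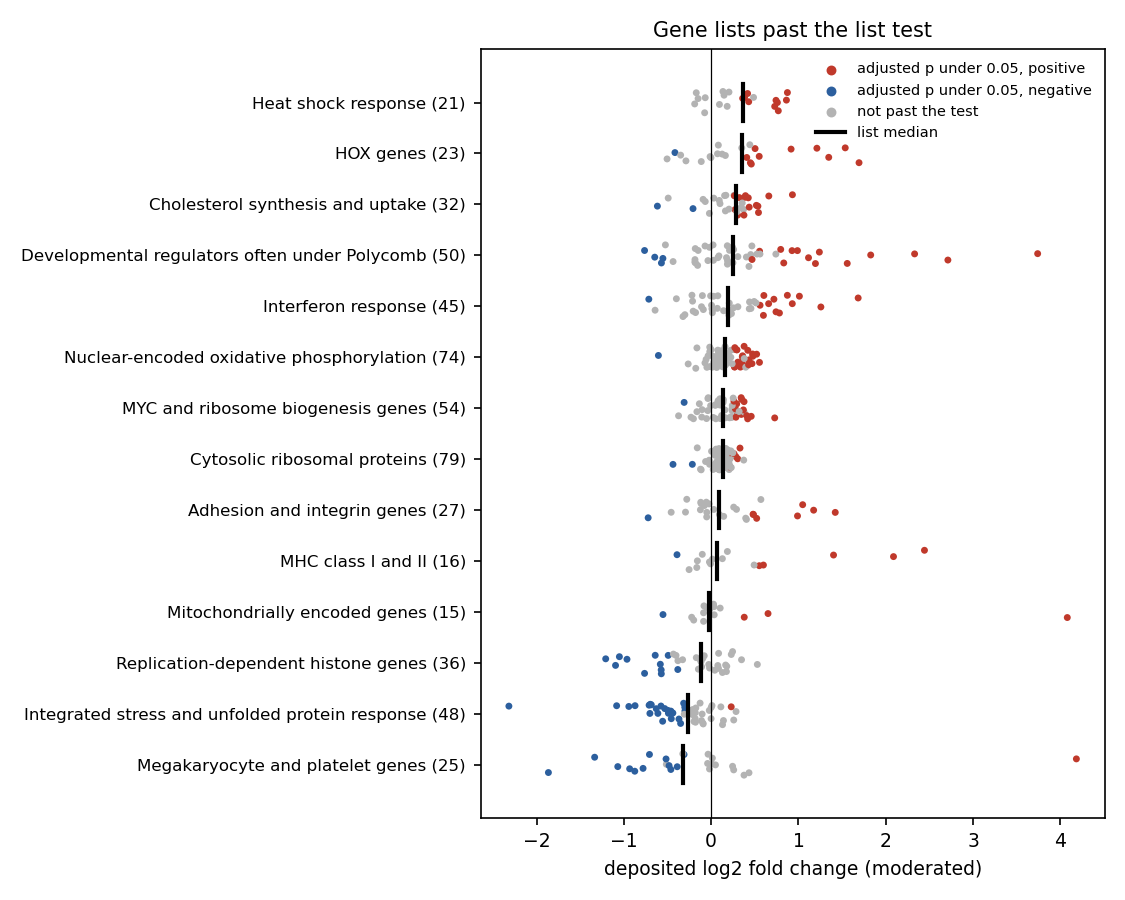
Deposited log2 fold change (moderated) of each measured member of the 14 gene lists past the list test, with the number of members in parentheses. Points are genes, coloured by the gene test, and black bars are list medians; the list test put the stress-response, megakaryocyte and histone lists on the negative side and the other 11 on the positive side, although the median of the mitochondrially encoded list is −0.02.

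Gene position was examined after the values were seen, and the bounds used here on chromosome 7 were set from the windows past the test. Among 404 windows of 5 Mb with at least 8 genes, 19 differed from the genome as a whole (resampling test, 100000 random draws of as many genes, adjusted p under 0.05). Of these windows, 17 lay on the negative side and 2 on the positive side, 8 of them on chromosome 7, 7 on chromosome 1 and 4 elsewhere. On chromosome 7 the median log2 fold change in the authors' deposited table was −0.006 over 288 genes before 105 Mb, −0.37 over 54 genes from 105 to 130 Mb, −0.84 (95% bootstrap interval −0.99 to −0.71) over 62 genes from 130 to 150 Mb, a ratio of 0.559, and −0.33 over 39 genes beyond. Of the 97 listed genes from 130 to 150 Mb, 58 passed the gene test on the negative side and 3 on the positive side. On chromosome 1 the median was −0.20 over 559 genes up to 121.2 Mb and 0.09 over 412 genes from 145.6 Mb on. Of the genes named in the text, CTH, JUN, SLC2A1, DIRAS3, PHC2 and LINC02780, all negative, and ID3, positive, lie in the part up to 121.2 Mb. Outside distal chromosome 7 and this part of chromosome 1, 1194 genes were positive and 988 negative, 54.7% positive against 49.5% over all genes. Both parts were chosen for their negative values, so this rise is by construction. Neighbouring genes are not independent, so the window p-values are too small where neighbours vary together.

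**Figure D3:**
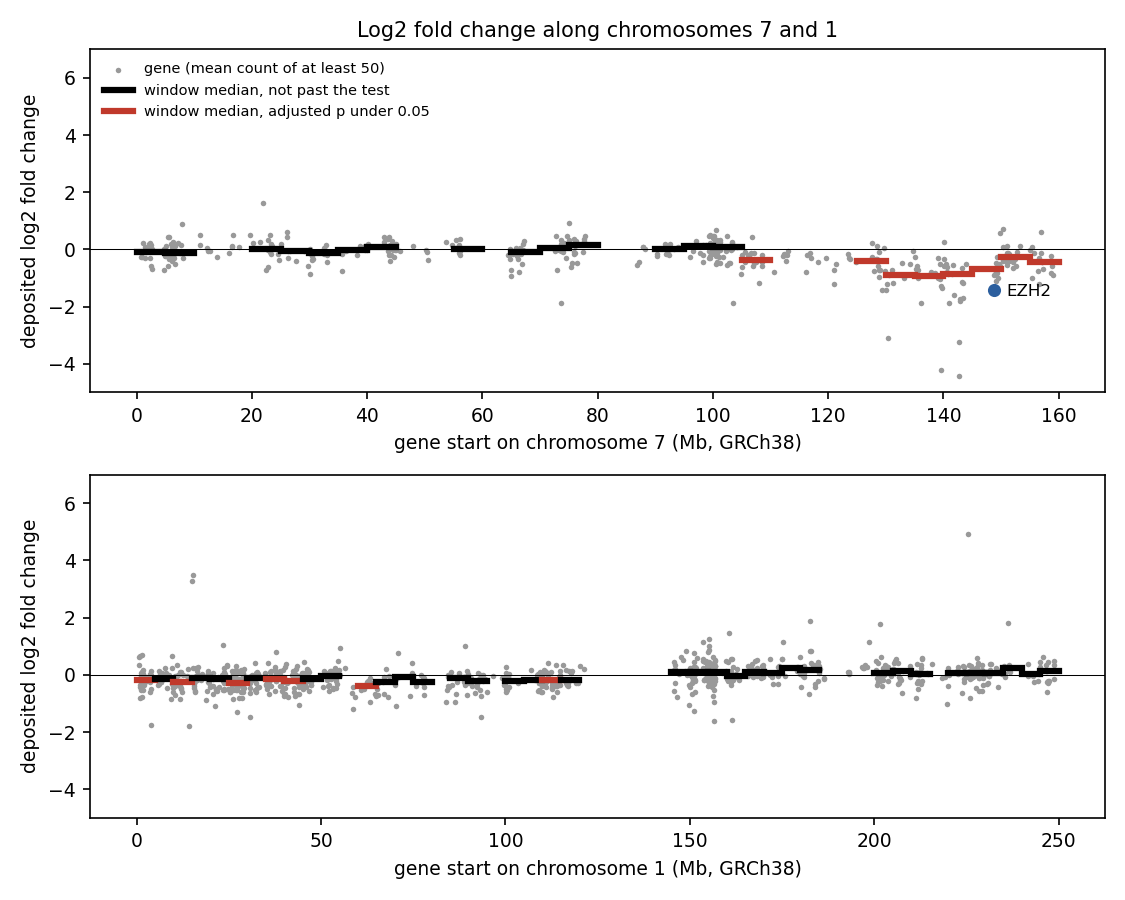
Deposited log2 fold change of genes with a mean count of at least 50 against their start on chromosomes 7 and 1 (Mb, GRCh38), with medians of 5-Mb windows as bars, red where the adjusted p is under 0.05. On chromosome 7 from 105 Mb on, 143 of 155 genes lie below 0, and the median is −0.84 from 130 to 150 Mb, where EZH2 lies.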

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

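The versions without the shifted parts of chromosomes 7 and 1, with protein-coding genes only, and without a list's most changed member were chosen only after the results were seen. No paired analysis was possible because the table has no values per library. For the same reason refits of count models, other normalisations and pseudocounts, leaving out libraries, the replicate block, fry, an estimated correlation, the spread between libraries and other splits of the samples were not run, so whether 1 library decides a call is open. Of the 2486 genes, 1641 had an adjusted p under 0.01 (802 positive, 839 negative) and 471 also had an absolute log2 fold change of at least 1 (252 positive, 219 negative), fewer by construction. Recomputed adjusted p-values gave 2488 genes, a mean count of at least 20 gave 2334 of 11018, and protein-coding genes alone 2197 of 11838. Of the 145 genes named by the rule, 12 lost their call at 0.01 and 81 at the fold bound, and 10 were not tested at a mean count of at least 20, where the other 135 stayed on their side of the threshold. Of 14 lists past the test, 9 kept their call with log2 fold changes (7 positive, 2 negative), 11 with ranks, 12 with a mean count of at least 20, 14 without the shifted parts, 11 without the most changed member and 10 against matched random lists. The developmental, interferon, cholesterol, oxidative phosphorylation, stress-response and heat shock lists passed in the same direction in each of these. HOX genes turned negative at a mean count of at least 20 (adjusted p = 0.76). Mitochondrially encoded genes turned negative with ranks (0.84), without MT-ND6 (1) and against matched lists (0.48). Outside the 14, germline genes passed at a mean count of at least 20 (0.043) and TGF-beta targets against matched lists (0.015). Of the 21 lists not past the test, 6 turned direction under at least 1 alternative without passing (erythroid, myeloid, stem and progenitor, fibroblast and other markers, immediate early, STAT5), the erythroid list without the shifted parts (0.082) among them. Except where 1 member was left out, the cause was not tested. Depth limits 4652 genes (29.7%) with a mean count under 20.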

Other observations

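The tests on distal chromosome 7, on unspliced RNA and on mitochondrial and short RNA were chosen only after the result was seen, while those of low counts and of the shifted chromosome parts among non-coding genes were set before theirs. Outside the lists and the shifted chromosome parts, several well-measured genes differed strongly in the authors' deposited table (DESeq2 adjusted p, mean count at least 500, chosen after their values were seen). On the positive side were the kinase PAK1 (2.23 ± 0.124, adjusted p = 2.3e-68), APOC1, an apolipoprotein (1.97 ± 0.130), NAV1 (1.79 ± 0.111), ABRACL (1.65 ± 0.124), SAMSN1 (1.35 ± 0.089) and PTPRC, which encodes the leukocyte phosphatase CD45 (1.15 ± 0.086). On the negative side were AIG1 (−1.45 ± 0.100), ALDH1A2, a retinoic acid-synthesising enzyme (−1.37 ± 0.083, adjusted p = 1.2e-57), CCDC115 (−1.07 ± 0.108), XACT, a long non-coding RNA of the X chromosome (−1.06 ± 0.095), GABPB1-AS1 (−1.05 ± 0.113) and ARHGAP18 (−0.89 ± 0.090).

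Values along distal chromosome 7 were lower over a broad stretch. From 105 Mb on, 143 of 155 genes with a mean count of at least 50 (92.3%) were negative, with a median of −0.51. Genes with lower counts were left out beforehand, so the tests here cannot speak for them. Among the genes kept, differences in mean count do not account for the shift. With values shuffled among genes of like mean count, the most shifted run of 155 neighbouring genes on any chromosome had a median between −0.11 and 0.15 (permutation test, two-sided p = 0.001, the smallest that 1000 shuffles can give). Within this stretch the shift was not confined to a few strong genes. The upper quartile was −0.26, below that of each run in 1000 such shuffles (lowest 0.07). Because the stretch was set from windows with negative medians, this quartile describes it and is no separate test. A lower copy number of this stretch in 1 kind of cells stays open as a candidate explanation: the stretch was chosen by its negative values, so the 92.3% cannot count for it, and DNA was not analysed here. EZH2, at −1.41, lay below the median of its stretch (−0.84), so how much of its value belongs to the gene and how much to the stretch was not separated.

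Long non-coding genes lay more often on the negative side: of 220 past the test, 181 were negative and 39 positive, against 46.7% negative among coding genes (Fisher's exact test, odds ratio 5.31, p = 2.3e-25, genes not being independent). Examples in the authors' deposited table are LINC00534 (−1.90), CCDC26 (−1.80), LINC02780 (−1.77) and BCAN-AS1 (−1.60), with LINC02573 (1.54) and MIR4458HG (0.75) on the positive side. Low counts do not account for the share of 82.3%, as called coding genes matched on mean count gave 36.8% to 49.5%, and outside the shifted chromosome parts it was still 80.3% (155 of 193). More unspliced RNA in 1 kind of cells stays open as a candidate explanation, seen before its test was set: 208 genes inside introns had a median of −0.038 (95% bootstrap interval −0.086 to −0.002) and longer coding genes had slightly lower statistics (Spearman's rho = −0.088 across 11838 genes). That shift is smaller than the median of antisense genes (−0.126), although the 8 genes inside introns past the gene test were all negative. No other explanation was tested.

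Transcripts of the mitochondrial light strand stood out on the positive side: the 4 such genes with a mean count of at least 20, MT-ND6 (4.08), MT-TC (3.10), MT-TY (2.25) and MT-TP (1.01), all passed, with a mean of 2.61 against 0.24 for 21 heavy-strand genes. More mitochondrial RNA in general does not account for it, as the 12 heavy-strand coding genes had a median of −0.067 (95% bootstrap interval −0.14 to 0.07). More capture of short RNA without a poly(A) tail stays open for mitochondrial RNA, since 4 of 7 heavy-strand tRNA genes, among them MT-TM (2.43) and MT-TV (1.32), were positive too, although 24 nuclear small RNA genes had a median of −0.15 (−0.37 to 0.07). More light-strand transcripts in 1 kind of cells stay open as well, because the 4 genes prompted this candidate explanation and cannot count for it. Without the strand setting of the counting, reads of the opposite strands cannot be separated, and no other biological explanation was tested.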
